A study of Mus musculus with 6 samples.

How the data were processed

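Total RNA from mouse fetal liver erythroid progenitors was measured on 6 single-colour Illumina bead arrays, 3 from progenitors carrying the SclRER/RER genotype, which encodes a form of SCL altered in its DNA binding, and 3 from wild-type (WT) progenitors. Per the labels' protocols, the cells came from embryos of day 12.5, were expanded in culture for 3 days and were then depleted of cells bearing Ter119, a surface marker of maturing red cells. RNA was amplified and labelled with biotin using a commercial kit, per the labels' protocols. Limma is named in the submitters' processing notes without a role or version, and the scanner software is not given in the sources used here. The labels give the strain as C57Bl/6 for both genotypes. Nothing in the labels says whether the 3 samples of a genotype came from separate embryos or cultures, so p-values measure only the spread between these samples, which may be technical in part. It was not technical alone, since Xist, Eif2s3y and Hprt lay too far apart among the SclRER/RER arrays for repeat measurements of 1 RNA sample.

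The deposited non-normalized table holds 1 signal intensity per probe and array on a linear scale for 46632 probes, per the file headers and the values, with no background subtraction and no scaling between arrays. Beside each signal the deposited table has a column headed as a detection p-value. Those columns rose with the adjacent signal (Spearman correlation of 0.996 or more on 5 arrays), so they were read as a deposited detection score, a fraction equal to 1 minus the detection p-value. The score column beside WT array 3 did not follow that array's signals. Its Spearman correlation was 0.899, and the score fell at 7.05% of steps when probes were ordered by signal, against 0 on the other 5 arrays. For WT array 3 each probe therefore received the mean score at the same signal rank on WT arrays 1 and 2, and the deposited scores were kept for an alternative. A further table of the authors holds linear intensity values quantile normalized between arrays, per the values, with a median of 83.7 on each array and the same order of probes as the non-normalized signals. It has no background subtraction and shows no centring of probes, and it was used as an alternative.

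Signals were processed in R 4.3.3 with limma 3.58.1. Background was corrected by the normal-exponential model with negative control parameters inferred from the detection scores, an offset of 16 was added, and arrays were quantile normalized and put on a log2 scale. Probes with a detection p below 0.01 on at least 3 of the 6 arrays were kept. A linear model with genotype as its only term was fitted with lmFit, and moderated two-sided tests from eBayes were adjusted by the Benjamini-Hochberg method over all kept probes, with an adjusted p below 0.05 taken as the threshold. All adjusted p-values of single genes below come from this limma fit. A positive log2 difference means a higher level in SclRER/RER. A probe with a detection p of 0.01 or more on every array of a genotype was called not detected there, and its difference is given as a bound. The bound sets the mean of the brighter genotype against the mean of the lowest signal among detected probes, or the probe's own signal where higher, on the arrays of the dimmer genotype. For named genes detected on only some arrays of a genotype, the difference was also computed with values below that lowest signal raised to it, a step added after seeing the data.

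Probes were named from the platform annotation, with symbols updated through gene identifiers in a table of the GRCm38.p6 assembly. Of the probes, 29976 had 1 gene symbol, 10 had several and 16646 had none, and 29921 had an identifier in that table. The build behind the array's design was not given, so no coordinates are printed and the table served only for names and for the order of genes along chromosomes. Each gene was represented by its kept probe with the highest mean log2 intensity over all 6 arrays.

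Before the data were examined, 29 gene lists were fixed from textbook knowledge. They covered SCL and its partners, erythroid transcription factors, globins, haem synthesis, iron handling, the red cell membrane, red cell enzymes and organelle clearance, erythropoietin and stem cell factor signalling, and stem and progenitor genes. Markers of megakaryocytes, mast cells, neutrophils, macrophages, lymphoid cells, hepatocytes, and endothelial and stromal cells were included because a fetal liver culture can hold them. The remaining lists were DNA replication, mitosis, cell cycle inhibitors and G1 regulators, cell death, helix-loop-helix inhibitors, ribosomal proteins, glycolysis, cholesterol synthesis, interferon response, amino acid and unfolded protein stress, immediate early and heat shock genes, sex-linked genes and common reference genes. Lists with at least 4 kept members, 25 in number, were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, and with fry, each adjusted over the lists by the Benjamini-Hochberg method. Changed members were counted over all kept probes and also adjusted over the list alone.

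Genes were named by a rule fixed at the same stage. It took Tal1, the 12 largest rises and 12 largest falls among changed genes whose 3 arrays of each genotype did not overlap and whose symbol was not a clone or predicted-gene name, and up to 4 changed members of each list by size. Where a list had no changed member, up to 2 kept members were taken as values only. All members of the SCL list and the globins, and members of patterns weighed in the closing section, were also named. Genes named outside this rule are said to have been chosen after their values were seen.

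Alternatives fixed before the data were examined were other background corrections and normalizations, the authors' normalized values, other detection filters, an intensity trend with a robust prior, array weights, the replicate number as a block, each array left out in turn, the mean of a gene's probes, and other thresholds. Both alternatives for WT array 3 and the alternative outside chromosomes 1, 7 and 8 were added after seeing the data. The fit was tested on 20 simulated data sets with 11578 probes, of which 200 were changed. It recovered 19.3% of changes of 0.5, 94.8% of changes of 1 and 99.9% of changes of 2 on the log2 scale, and 6.55% of its calls were false. Over simulated lists, camera made 1 false call in 20 sets with the preset correlation and 0 with the estimated one, and a list shifted by -0.5 was recovered 20 and 19 times. The simulated genes varied independently, so these counts do not give the error rate for lists of correlated genes. In the measured data the estimated correlation of a list reached 0.73 (neutrophil and granule genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Depth does not apply to these arrays, and the 3 arrays per genotype limit the precision.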

Results

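Gene expression was compared between SclRER/RER and WT fetal liver progenitors to ask which genes depend on direct DNA binding by SCL, the product of Tal1. SCL is a basic helix-loop-helix transcription factor required for blood formation. Each genotype had 3 arrays. Mean signal was between 385 and 546 intensity units per array, and between 11084 and 12678 of the 46632 probes were detected. Pairs of SclRER/RER arrays correlated across kept probes with Pearson r of 0.975 to 0.984 and pairs of WT arrays with 0.989 to 0.993, while pairs across genotypes lay between 0.959 and 0.973. The median SD of a probe was 0.17 in SclRER/RER and 0.13 in WT on the log2 scale.

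Tal1 mRNA itself was measured at 12.77 ± 0.04 in SclRER/RER and 12.69 ± 0.12 in WT (log2 intensity, mean ± SD, n = 3 each). The difference of 0.08 (SE 0.11, 95% confidence interval -0.18 to 0.34) did not pass the test, with a limma adjusted p of 0.77. An exact two-sided permutation test gave p = 0.4, where 3 arrays against 3 allow no p below 0.1. The mutation alters the protein's DNA binding and need not alter its mRNA, so this level is no check of the genotype labels.

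Progenitors with the DNA-binding mutant of SCL had lower mRNA for several erythroid and platelet-lineage genes and a set of individual genes shifted by large factors in both directions. Slc4a1, the band 3 anion exchanger of the red cell membrane, fell by 2.35 on the log2 scale (SE 0.29, adjusted p = 0.00202), and Ppbp, a platelet chemokine, fell by 1.88 (SE 0.15, adjusted p = 0.000245). Mmp2, a gelatinase, rose by 3.84 (SE 0.16, adjusted p = 6.87e-06). Of 6855 genes tested, 451 changed, 245 higher and 206 lower in SclRER/RER, and 184 of them differed by at least 2-fold. Of 11578 kept probes 762 changed, 385 higher and 377 lower, with 2268 at an unadjusted p below 0.05. All 451 changed genes had non-overlapping values between genotypes, as did 25.4% of all tested genes, where chance gives 10%. The count of changed genes was 297 without SclRER/RER array 2, 192 without WT array 2 and 212 without WT array 3, and 316 of 5592 genes changed outside chromosomes 1, 7 and 8. That last count takes in genes with no place on a chromosome sequence, Hbb-b2 among them.

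**Figure D1:**
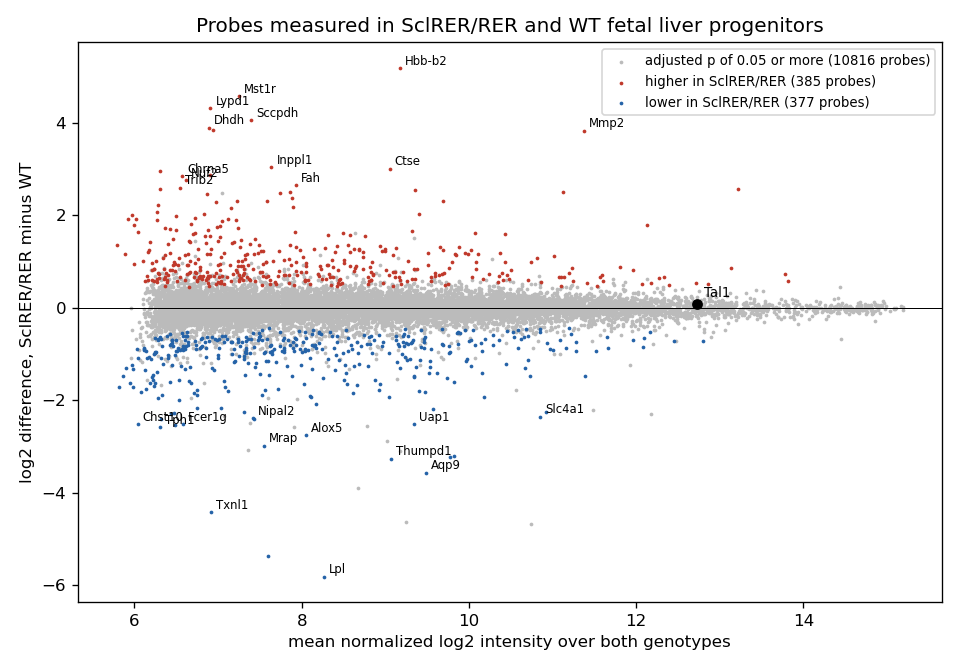
Log2 difference between SclRER/RER and WT (vertical axis) against mean normalized log2 intensity (horizontal axis) for 11578 kept probes, 1 point per probe. Red points are the 385 probes higher and blue points the 377 probes lower in SclRER/RER, the 12 genes with the largest rise and the 12 with the largest fall are named, and the black point is Tal1 at 0.08.

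The largest rise was that of the Hbb-b2 probe, for an adult beta-globin chain, at 5.19 on the log2 scale (36.5-fold, SE 0.21, adjusted p = 6.87e-06). It lay at 11.77 ± 0.37 in SclRER/RER and 6.58 ± 0.28 in WT (n = 3 each), where it was detected on 2 of the 3 arrays. Hbb-b2 is not on the chromosome sequence of the C57BL/6J reference. A beta-globin haplotype of another strain is therefore a candidate explanation, weighed in the closing section. Mmp2 rose 14.3-fold, from 9.45 ± 0.11 to 13.29 ± 0.28. Ctse, the aspartic protease cathepsin E, rose by 3.01 (SE 0.33, adjusted p = 0.0013) and Fah, the last enzyme of tyrosine breakdown, by 2.65 (SE 0.17, adjusted p = 6.61e-05). The other 8 of the 12 largest rises were in genes detected on no WT array, so each is a bound. Mst1r, the receptor tyrosine kinase RON, was at least 8.96-fold higher (adjusted p = 9.5e-07). Sccpdh was at least 8.28-fold higher, Inppl1, the inositol phosphatase SHIP2, at least 6.90-fold, Lypd1 at least 6.48-fold and Dhdh at least 5.53-fold. Nuf2, a kinetochore protein, was at least 3.10-fold higher, Chrna5, a nicotinic receptor subunit, at least 3.08-fold and the pseudokinase gene Trib2 at least 2.78-fold.

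Lpl, encoding lipoprotein lipase, had the largest fall. It was at 11.17 ± 0.20 in WT and detected on no SclRER/RER array, a difference of at least 30.2-fold (adjusted p = 8.23e-06). Txnl1, a thioredoxin-like protein, was at least 7.32-fold lower, Tph1, which makes serotonin from tryptophan, at least 2.53-fold lower, and Chst10, a sulfotransferase, at least 2.07-fold lower. Aqp9, a water and glycerol channel, fell by 3.56 (SE 0.19, adjusted p = 2.59e-05) and Alox5, the arachidonate lipoxygenase that starts leukotriene synthesis, fell by 2.75 (SE 0.16, adjusted p = 3.94e-05). Log2 differences were -2.38 (SE 0.16) for Nipal2, -2.98 (SE 0.51) for Mrap, the melanocortin receptor accessory protein, -2.51 (SE 0.44) for Fcer1g, the shared gamma chain of Fc receptors, -3.26 (SE 0.81) for Thumpd1 and -2.51 (SE 0.61) for Uap1. Fcer1g and Nipal2 were detected on 1 of the 3 SclRER/RER arrays and Mrap and Thumpd1 on 2, and with values below the detection floor raised to it the differences were -1.51 for Fcer1g, -2.15 for Nipal2, -2.39 for Mrap and -3.09 for Thumpd1. The calls of Thumpd1 and Uap1 were not stable. Thumpd1 had values of 9.73, 5.91 and 6.66 on SclRER/RER arrays 1 to 3, and its adjusted p rose to between 0.106 and 0.175 on leaving out any array other than SclRER/RER 1. Uap1 had values of 7.25, 7.18 and 9.82, and its adjusted p rose to between 0.0982 and 0.16 on leaving out any array other than SclRER/RER 3. Fcer1g missed the threshold without WT array 2 (adjusted p = 0.0604) or WT array 3 (0.0588), and Mrap without WT array 3 (0.0572).

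Among 16 genes of the SCL list, which holds SCL with its DNA-binding partners and cofactors, 1 rose, 0 fell and 15 did not pass. Adjusted over the list alone, 2 were higher and 2 lower. The list's median difference was 0.02 (camera adjusted p = 0.95). Tcf4, an E protein that pairs with SCL, rose by 0.84 (SE 0.13, adjusted p = 0.00786), which missed the threshold without WT array 2 (adjusted p = 0.0544). The other E proteins differed by 0.09 (Tcf3) and -0.01 (Tcf12). Differences were 0.19 for Lmo2 and 0.15 for Ldb1, the bridging proteins of the complex, 0.00 for Lmo4, 0.21 for Lyl1, the closest relative of SCL, -0.23 for Gata1 and 0.04 for Gata2. Runx1, a partner in progenitors, differed by 0.47 (SE 0.12, adjusted p = 0.0533), and its adjusted p was 0.0283 without SclRER/RER array 3. Ssbp2 differed by -0.42 (adjusted p = 0.0635) and Ssbp3 by -0.40 (0.0666) on its brightest probe, while its other kept probe passed at -0.48 (adjusted p = 0.0437). These genes lay close to the threshold, which Runx1 passed under 8, Ssbp2 under 6 and Ssbp3 under 7 of 20 alternatives, the authors' normalized values among them (adjusted p = 0.034, 0.0314 and 0.0297). Gfi1b differed by -0.18 and Sp1 by -0.40. Cbfa2t3, the corepressor ETO2, differed by -0.50 (SE 0.24, adjusted p = 0.297), and by -0.82 (adjusted p = 0.00505) without SclRER/RER array 3.

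Of 15 erythroid transcription factors tested, 0 rose and 1 fell. Adjusted over the list alone, 1 was higher and 1 lower (camera adjusted p = 0.793). The member that fell was E2f2, a cell cycle factor of maturing erythroblasts, by 0.91 (SE 0.11, adjusted p = 0.00192).

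Genes of haem synthesis were lower as a group. Of 17 tested, 0 rose, 2 fell and 15 did not pass, and 5 were lower when adjusted over the list alone. The median difference was -0.18, with a camera adjusted p of 0.000276 at the preset correlation and an adjusted p = 0.177 with an estimated correlation. The median was -0.28 without SclRER/RER array 2 and -0.28 without WT array 1, still past the threshold at the preset correlation, where the cause was not tested. Over all 20 alternatives it ranged from -0.30 to -0.16. Slc25a37, the mitochondrial iron importer mitoferrin, fell by 0.82 (SE 0.15, adjusted p = 0.0162). Ppox, the enzyme that makes protoporphyrin, fell by 0.78 (SE 0.16, adjusted p = 0.0243), with only some of its probes passing. Slc25a37 missed the threshold without WT array 1 (adjusted p = 0.0536) or WT array 3 (0.0758), and Ppox on leaving out any array other than SclRER/RER 3 (0.0559 to 0.11). Of 12 iron uptake and storage genes, 0 passed, also when adjusted over the list alone (camera adjusted p = 0.403). Tfrc, the transferrin receptor, differed by -0.48 (SE 0.15, adjusted p = 0.105), and Aco1, an iron-sensing aconitase, by 0.33 (SE 0.30, adjusted p = 0.627), which became 0.73 (adjusted p = 0.0291) without SclRER/RER array 3.

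Red cell membrane and cytoskeleton genes also shifted down, with 0 of 23 rising, 3 falling and 20 not passing, and 8 lower when adjusted over the list alone. The median difference was -0.23 (camera adjusted p = 0.000557, and adjusted p = 0.177 with an estimated correlation). Slc4a1 stood at 9.68 ± 0.57 in SclRER/RER and 12.03 ± 0.36 in WT (n = 3 each), a 5.11-fold higher level in WT. Tspo2, an erythroid translocator protein, fell by 1.41 (SE 0.22, adjusted p = 0.00708), a call lost with no detection filter (adjusted p = 0.0581). Tmod1, which caps actin filaments in the membrane skeleton, fell by 0.64 (SE 0.16, adjusted p = 0.045), a call lost on leaving out any array other than SclRER/RER 3 (adjusted p between 0.0996 and 0.146). Of 14 red cell enzyme and organelle clearance genes, 1 rose and 1 fell, and 1 was higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.195). Prdx2, an abundant red cell peroxiredoxin, fell by 2.08 (SE 0.17, adjusted p = 0.000218) on its brightest probe. Its other kept probe was detected on no SclRER/RER array and was at least 16.3-fold lower (adjusted p = 6.43e-08), and the mean of both probes differed by -3.72. Xpo7, an exportin of maturing erythroblasts, rose by 0.68 (SE 0.16, adjusted p = 0.0384), a call lost without SclRER/RER array 2 (adjusted p = 0.115), SclRER/RER array 3 (0.0733), WT array 2 (0.141) or WT array 3 (0.132). Xpo7 was detected on 1 of the 3 WT arrays, and its difference was 0.46 with values raised to the detection floor.

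Of 4 globin and globin chaperone genes tested, 1 rose, Hbb-b2 with the limit given above, and 3 did not pass, as also when adjusted over the list alone (camera adjusted p = 0.236). The brightest probes of the other adult globins did not pass. Hba-a1 differed by 0.09 (SE 0.12), Hbb-bt by 0.03 (SE 0.11) and Hbb-bs by -0.14 (SE 0.13), with adjusted p of 0.765, 0.923 and 0.661. In WT these probes lay at 14.82 to 14.97, against 15.26 for the highest value on any array, so a large rise could not have been measured on them. Of the 5 kept probes of Hbb-bs, the dimmest, at 12.94 in WT and 2.33 below the highest value, differed by 0.18 (SE 0.14, adjusted p = 0.551). Another differed by -0.68 (adjusted p = 0.292), with levels of 14.87, 13.33 and 14.12 on the SclRER/RER arrays. Of the 5 kept probes of Hbb-bt, 1 differed by -2.87 (adjusted p = 0.104), with levels over 8-fold apart between SclRER/RER arrays.

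**Figure D2:**
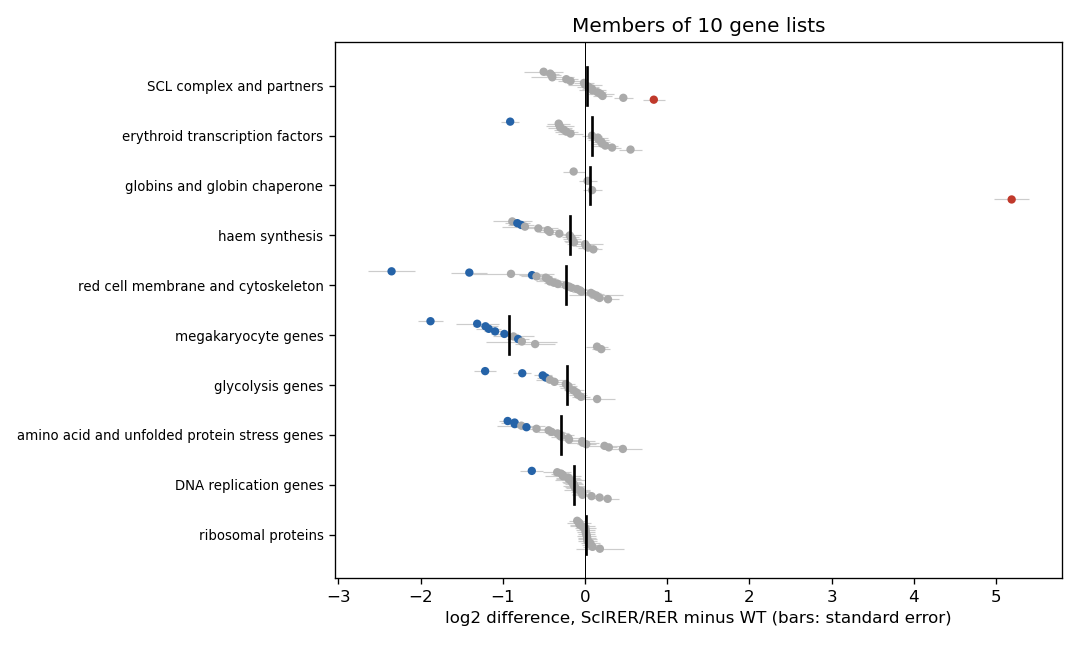
Log2 difference between SclRER/RER and WT (horizontal axis) of each tested member of 10 gene lists, 1 point per gene with its standard error as a bar, red where higher, blue where lower and grey where the test was not passed. Black lines are list medians, which lay at -0.92 for megakaryocyte genes, -0.23 for red cell membrane genes and 0.02 for ribosomal proteins.

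Megakaryocyte genes showed the strongest downward shift of the lists tested. Of 12 measured above background, 0 rose, 7 fell and 5 did not pass, and 9 were lower when adjusted over the list alone. The median difference was -0.92 (camera adjusted p = 1.95e-07, and adjusted p = 0.185 with an estimated correlation), and -0.61 with no detection filter. Besides Ppbp, Treml1, a receptor of platelet granules, fell by 1.21 (SE 0.15, adjusted p = 0.00235), Alox12, the platelet lipoxygenase, by 1.17 (SE 0.15, adjusted p = 0.003), and Pf4, platelet factor 4, by 1.31 (SE 0.26, adjusted p = 0.0207). Pf4 missed the threshold without WT array 2 (adjusted p = 0.0972) or WT array 3 (0.0773).

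Other blood lineages moved gene by gene. Of 11 neutrophil and granule genes 3 fell, as also when adjusted over the list alone, with 0 higher. These were the granule proteases Ctsg (-1.62, SE 0.21, adjusted p = 0.00297, detected on 1 of the 3 SclRER/RER arrays, and -1.14 with values raised to the detection floor) and Prtn3 (-0.68, SE 0.16, adjusted p = 0.0416) and the peroxidase Mpo (-0.63, SE 0.14, adjusted p = 0.0338). Mpo and Prtn3 missed the threshold without SclRER/RER array 2 (adjusted p = 0.056 and 0.0901), WT array 1 (0.0839 and 0.092), WT array 2 (0.153 and 0.182) or WT array 3 (0.112 and 0.115). The list as a whole had a median of -0.09 (camera adjusted p = 0.179), and of -0.52 (0.000376) without SclRER/RER array 1. Of 8 mast cell and basophil genes, 1 rose and 2 fell, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.318). Tph1 and Fcer1g fell, as above, while Cpa3, the mast cell carboxypeptidase, rose by 1.07 (SE 0.19, adjusted p = 0.0127; detected on 1 of the 3 WT arrays, and 0.84 with values raised to the detection floor), which missed the threshold without WT array 2 (adjusted p = 0.0519). Fcer1g missed it without WT array 2 (0.0604) or WT array 3 (0.0588).

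Markers of cells outside these lineages were mostly below detection. Of 28 macrophage and monocyte genes 4 were measured above background, and 1 rose, as also when adjusted over the list alone (camera adjusted p = 0.572). This was the Fc receptor gene Fcgr3, detected on no WT array and at least 1.52-fold higher (adjusted p = 0.0329), a call lost on leaving out any array other than SclRER/RER 3 (adjusted p between 0.0536 and 0.147). Of 23 lymphoid genes 0 were kept and of 26 hepatocyte genes 1 was kept, Apoa1, at -0.49 (SE 0.22, adjusted p = 0.264). Of 23 endothelial and stromal genes 3 were kept and 0 passed, with 1 lower when adjusted over the list alone. Egfl7 differed by -0.47 (SE 0.14, adjusted p = 0.101) on its brightest probe, and by -0.60 (adjusted p = 0.0269) without SclRER/RER array 3. Its other kept probe passed at -0.61 (adjusted p = 0.0424). Kdr, a receptor for vascular growth factor, differed by -0.30 (SE 0.17, adjusted p = 0.391). Of 10 stem and progenitor genes 0 rose and 1 fell, with 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.745). Cd34, a surface marker of progenitors, was detected on no SclRER/RER array and was at least 1.24-fold lower (adjusted p = 0.00651).

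Erythropoietin and stem cell factor signalling genes changed in both directions. Of 16 tested, 4 rose and 2 fell, with 5 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.745). Osm, encoding the cytokine oncostatin M, rose by 1.36 (SE 0.13, adjusted p = 0.00062), Erfe, the erythroid hormone that lowers hepcidin, by 0.84 (SE 0.17, adjusted p = 0.0225), and Gab1, a docking protein of growth factor receptors, by 0.75 (SE 0.12, adjusted p = 0.00753). The other riser was Cish, a target of Stat5 (0.48, SE 0.11, adjusted p = 0.0442), and the other gene that fell was Epor, the erythropoietin receptor (-0.54, SE 0.11, adjusted p = 0.0199), with only some of its probes passing. Both were named after their values were seen, and their calls were lost on leaving out any array other than SclRER/RER 3 for Cish (adjusted p between 0.0957 and 0.154), and without SclRER/RER array 2 or WT array 1, 2 or 3 for Epor (0.0685 to 0.0787). Igf1r, the receptor of insulin-like growth factor, fell by 0.61 (SE 0.15, adjusted p = 0.047), with only some of its probes passing. Erfe missed the threshold without SclRER/RER array 1 (adjusted p = 0.0503), SclRER/RER array 2 (0.0754), WT array 2 (0.118) or WT array 3 (0.1), Gab1 without WT array 2 (0.0547), and Igf1r without SclRER/RER array 2 (0.119), SclRER/RER array 3 (0.0868), WT array 2 (0.175) or WT array 3 (0.173).

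Glycolysis genes were lower as a group. Of 14 tested, 0 rose, 4 fell and 10 did not pass, with 5 lower when adjusted over the list alone. The median was -0.22 (camera adjusted p = 4.73e-05, and adjusted p = 0.208 with an estimated correlation). Pdk1, which restrains pyruvate entry into the citric acid cycle, fell by 1.21 (SE 0.13, adjusted p = 0.00134), with only some of its probes passing, and Egln3, an oxygen-sensing prolyl hydroxylase, by 0.76 (SE 0.11, adjusted p = 0.00431). Neither is itself an enzyme of glycolysis. The glycolytic enzymes Pkm and Pfkp fell by 0.51 (SE 0.11, adjusted p = 0.0304) and 0.48 (SE 0.11, adjusted p = 0.0404). The call of Pkm was lost without SclRER/RER array 2 (adjusted p = 0.106), WT array 1 (0.0846), WT array 2 (0.144) or WT array 3 (0.104), and that of Pfkp, of which only some probes passed, on leaving out any array other than SclRER/RER 3 (0.0598 to 0.15).

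Amino acid and unfolded protein stress genes were lower too, with 0 of 19 rising, 4 falling and 15 not passing, and 5 lower when adjusted over the list alone. The median was -0.30 (camera adjusted p = 0.000276, and adjusted p = 0.185 with an estimated correlation). Slc7a11, the cystine transporter, fell by 0.94 (SE 0.10, adjusted p = 0.00123), Herpud1, a factor in the breakdown of misfolded proteins, by 0.85 (SE 0.11, adjusted p = 0.00258), Trib3 by 0.86 (SE 0.16, adjusted p = 0.018) and Asns, asparagine synthetase, by 0.71 (SE 0.16, adjusted p = 0.0366). Trib3 and Asns missed the threshold without SclRER/RER array 2 (adjusted p = 0.0605 and 0.0887), WT array 1 (0.058 and 0.0751), WT array 2 (0.0641 and 0.164) or WT array 3 (0.0796 and 0.116).

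Of 22 DNA replication genes, 1 fell, as also when adjusted over the list alone, and 0 rose, with a median of -0.13 (camera adjusted p = 0.0431, and adjusted p = 0.673 with an estimated correlation). The list missed the threshold without SclRER/RER array 1 (camera adjusted p = 0.0627), SclRER/RER array 2 (0.289), WT array 1 (0.0594), WT array 2 (0.0552) or WT array 3 (0.0774). It missed it also with median centring (0.113), with cyclic loess (0.0588) and outside chromosomes 1, 7 and 8 (0.214). The member that fell was Rrm1, a ribonucleotide reductase subunit, by 0.65 (SE 0.14, adjusted p = 0.0307), a call lost without SclRER/RER array 2 (adjusted p = 0.0805), WT array 1 (0.0911), WT array 2 (0.102) or WT array 3 (0.121). Of 16 mitosis genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.553). Nusap1, a spindle protein, differed by 0.50 (adjusted p = 0.197), and by 0.69 (adjusted p = 0.0429) without SclRER/RER array 3. Bub1b, a spindle checkpoint kinase, differed by -0.43 (adjusted p = 0.173), and by -0.61 (adjusted p = 0.026) without SclRER/RER array 1. Of 16 cyclin-dependent kinase inhibitors and G1 regulators, 1 fell, again E2f2, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.403).

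The remaining lists gave few or no calls. Of 11 immediate early and heat shock genes 2 rose, as also when adjusted over the list alone (camera adjusted p = 0.318), the phosphatase gene Dusp1 by 0.71 (SE 0.12, adjusted p = 0.0115) and the transcription factor Jun by 0.70 (SE 0.13, adjusted p = 0.0145), Jun being detected on 2 of the 3 WT arrays, and both calls were lost without WT array 2 (adjusted p = 0.07 and 0.086). Of 5 interferon response genes Psmb8, an immunoproteasome subunit, rose by 0.69 (SE 0.16, adjusted p = 0.0425), with only some of its probes passing, and the call was lost on leaving out any array other than SclRER/RER 3 (adjusted p between 0.0658 and 0.145). It was also the 1 member higher when adjusted over the list alone (camera adjusted p = 0.403). Of 10 helix-loop-helix and inhibitor genes 1 rose, Tcf4, as also when adjusted over the list alone (camera adjusted p = 0.854, and adjusted p = 0.0544 for Tcf4 without WT array 2). No member passed among 16 ribosomal protein genes (median 0.02, camera adjusted p = 0.994), 15 cholesterol synthesis genes (median 0.10, camera adjusted p = 0.657) or 10 cell death and survival genes (median -0.03, camera adjusted p = 0.994), nor when adjusted over each list alone. Examples were Rps19 at 0.18 (SE 0.29), Rpl13 at -0.09 (SE 0.11), Hmgcs1 at 0.33 (SE 0.12), Sc5d at 0.27 (SE 0.18), Pim1 at -0.37 (SE 0.16) and Dapk1 at 0.83 (SE 0.26), which passed without SclRER/RER array 3 (1.10, adjusted p = 0.019).

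In all, 6 of the 25 lists tested passed with camera at the preset correlation, all lower in SclRER/RER, and 0 passed with the correlation estimated. The estimated correlations of the haem synthesis list (0.0036) and the red cell membrane list (0.0024) were below the preset 0.01. For those lists a higher correlation was therefore not what ended the call. With fry, which tests a list without comparing it with other genes, 7 lists passed for a shift in 1 direction and 19 for change in either direction. Outside chromosomes 1, 7 and 8 the red cell membrane list had 3 of 22 genes falling and the haem synthesis list 1 of 11. The glycolysis list kept 4 falls and the amino acid and unfolded protein stress list 3. The falls of Tph1, Fcer1g, Prdx2, Cd34, Rrm1, Ppox, Herpud1 and Igf1r lay on those chromosomes and dropped out of their lists. So did the rises of Fcgr3, Erfe and Gab1. Erythropoietin and stem cell factor signalling genes were left with 2 higher and 1 lower. All 12 tested megakaryocyte genes lie outside those chromosomes, so that setting did not test their list.

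Of 10 reference genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.367), but Hprt, a purine salvage enzyme encoded on the X chromosome, differed between arrays of the same genotype. Its brightest probe read 6.56, 5.64 and 13.02 on SclRER/RER arrays 1 to 3 and between 12.89 and 13.20 on WT arrays, a mean difference of -4.66 (SE 1.59, adjusted p = 0.14). Without SclRER/RER array 3 the difference was -6.97 (adjusted p = 9.55e-06). The other kept Hprt probes went the same way. They read 4.87, 4.74 and 6.84, and 4.95, 4.75 and 10.49, on SclRER/RER arrays 1 to 3, against 6.7 to 7.4 and 10.4 to 10.9 on WT arrays. Both sex-linked genes that were kept also varied within genotypes, and 0 passed, also when adjusted over the list alone. Xist, expressed from the inactive X chromosome, was at 5.89, 11.03 and 10.47 on the SclRER/RER arrays and 10.98, 9.02 and 10.61 on the WT arrays. Eif2s3y, a gene of the Y chromosome, was at 9.89, 4.75 and 5.48 on the SclRER/RER arrays and 6.12, 9.25 and 7.77 on the WT arrays. In SclRER/RER, Hprt and Xist were detected on 2 of the 3 arrays and Eif2s3y on 1, and in WT Eif2s3y was detected on 2.

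**Figure D3:**
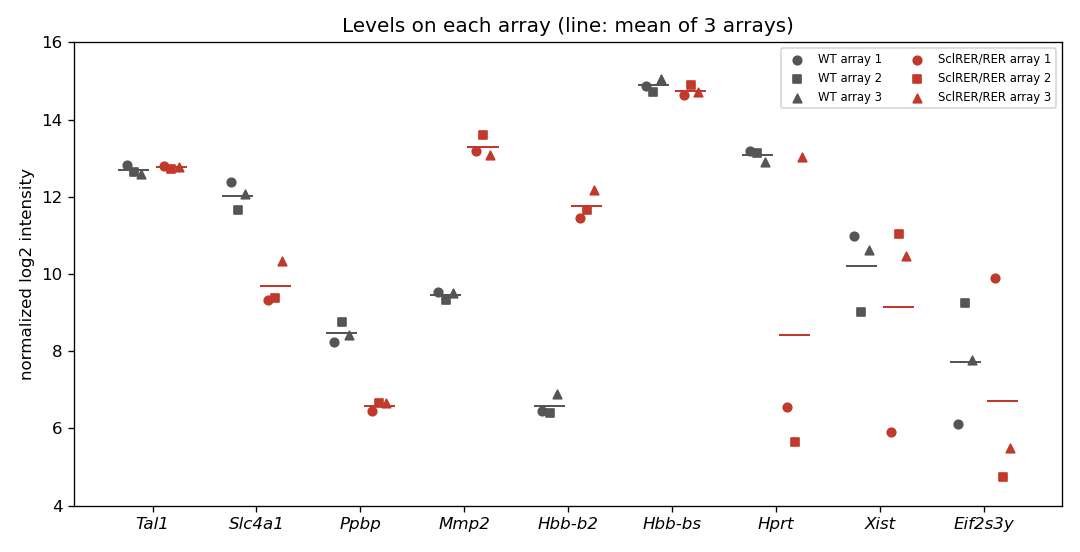
Normalized log2 intensity (vertical axis) of 9 genes on each array, with a symbol shape for each array number, WT in grey, SclRER/RER in red, and a line at the mean of 3 arrays. Tal1 overlaps between genotypes, Hbb-b2 is near 11.77 in SclRER/RER against 6.58 in WT, and Hprt on SclRER/RER array 3 lies at 13.02 beside 6.56 and 5.64 on the other SclRER/RER arrays.

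Changed genes were spread unevenly over chromosomes. In Fisher's exact tests adjusted over 20 chromosomes, chosen after the data were seen, the share of tested genes that changed was above that of the other chromosomes on chromosome 7 (57 of 544 genes, 10.5%, adjusted p = 0.00552), chromosome 8 (43 of 390, 11.03%, adjusted p = 0.00654) and chromosome 1 (35 of 329, 10.6%, adjusted p = 0.0265). It was below on chromosome 5 (17 of 469, 3.63%, adjusted p = 0.0325). Of the largest rises and falls named above, Mmp2 lay on chromosome 8 and Fah, Inppl1 and Thumpd1 on chromosome 7. Ctse, Lypd1, Sccpdh, Dhdh, Nuf2, Lpl, Tph1, Chst10, Uap1 and Fcer1g also lay on chromosome 1, 7 or 8. Most of the largest rises and falls therefore lay on these chromosomes. With them set aside, 5592 of the 6855 tested genes were left. On chromosome 4, 14 of the 100 tested genes nearest to Tal1 changed, against 6.43% of the other genes (one-sided Fisher's exact p = 0.00528).

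**Figure D4:**
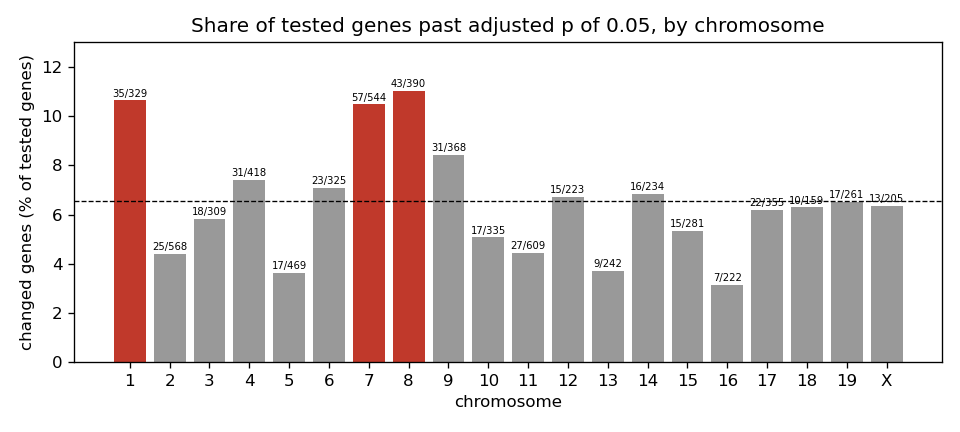
Share of tested genes that changed (vertical axis, percent) on each chromosome (horizontal axis), with the numbers of changed and tested genes above each bar and a dashed line at the share over all chromosomes, 6.54%. Red bars mark chromosomes 1, 7 and 8, at 10.6%, 10.5% and 11.03%.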

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

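The tests outside chromosomes 1, 7 and 8 and both alternatives for WT array 3 were chosen after the data were seen, and the others before. Those for WT array 3 used its deposited scores, or a detection filter on the other arrays only. Array weights raised the counts to 1209 probes and 704 genes, and an adjusted p below 0.01 lowered them to 299 probes and 188 genes, by its own construction. With no detection filter 308 genes changed, of which 256 were among the 451. Leaving out 1 array at a time gave 301 to 986 probes and 192 to 604 genes, with fewer samples in each fit. The number of lists passing with camera was 5 to 7 over 20 alternatives. The DNA replication list, at a median of -0.13, missed the threshold with median centring (-0.12), cyclic loess (-0.14) and outside chromosomes 1, 7 and 8 (-0.13), and on leaving out an array its median ranged from -0.19 to -0.10, where the cause was not tested. The medians of the other lists that passed stayed below 0 and past the threshold under all 20 alternatives at the preset correlation, but with the correlation estimated 0 of 25 lists passed. The Tal1 difference lay between 0.04 and 0.15 and never passed. Of 1970 values of named genes under alternatives, 1788 stayed on their side of the threshold, 142 lost a call, 97 of them on leaving out an array and 23 with no detection filter, where all 46632 probes were tested, 40 gained one and 0 changed sign while called. With no detection filter the calls lost were those of Thumpd1, Mrap, Uap1, Fcer1g, Slc25a37, Ppox, Tspo2, Tmod1, Xpo7, Erfe, Igf1r, Pf4, Cpa3, Prtn3, Mpo, Fcgr3, Rrm1, Psmb8, Trib3, Asns, Vwf, Cish and Sphk1. Leaving out arrays aside, calls were gained in some setting by Runx1, Ssbp2, Ssbp3, Gp5, Egfl7, Tfrc, Bub1b, Dapk1 and Hprt. Among those that stayed, 17 changed sign without passing in either setting. Of 68 named genes that changed, 39 kept their call whichever array was left out. The replicate numbers were tested as a block, with 726 probes and 432 genes changed. Among named genes that block ended the calls of Tmod1, Xpo7, Igf1r, Pf4, Pkm, Pfkp, Psmb8 and Cish, and Dapk1 gained one. Deviations of same-numbered arrays correlated at 0.16, -0.03 and 0.07, and 3 of the 6 arrays correlated best with their own number, so the numbers are not taken to pair samples. No chip identifier was used here, so a chip block was not run. Signal over background limits the dim probes, since differences there are bounds.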

Other observations

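Tests chosen only after the result was seen were those of the beta-globin probes and of the megakaryocyte falls, and the genes of the first paragraph were also chosen after their values were seen. The anchor of the beta-globin neighbour test was corrected after a first value had been seen, as said beside it.

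Examples follow from the next 12 largest changes in each direction, picked with no test of a common theme. Smad1, a transducer of bone morphogenetic protein signals, was detected on no WT array and was at least 3.33-fold higher in SclRER/RER (limma adjusted p = 0.000218). Gdf3, a ligand of the same family, rose by 2.50 on the log2 scale (SE 0.19, adjusted p = 0.000182), from 9.88 ± 0.16 to 12.37 ± 0.38 (SD, n = 3 each). Pax6, a transcription factor of eye and brain, rose by 2.32 (SE 0.28, adjusted p = 0.00205) and Inpp4b, an inositol phosphatase, by 2.48 (SE 0.28, adjusted p = 0.0014), although another Inpp4b probe differed by 0.34 and the brighter one was detected on 2 of the 3 WT arrays. Among the falls, Sphk1, which makes sphingosine 1-phosphate, differed by -2.25 (SE 0.44, adjusted p = 0.0191, and 0.0558, 0.0815 and 0.0758 without WT arrays 1, 2 and 3) on its brightest probe and was at least 1.18-fold lower on its other kept probe, which was detected on no SclRER/RER array. Stx11, a syntaxin of granule release, differed by -2.20 (SE 0.14, adjusted p = 7.64e-05) and Gsta4, a glutathione transferase, by -1.92 (SE 0.10, adjusted p = 2.63e-05).

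Changed genes lay close together along chromosomes. Of the 100 tested genes nearest to Tal1, 14 changed against 6.43% elsewhere (one-sided Fisher's exact p = 0.00528), and 46 pairs of changed genes were neighbours, against a median of 29 in 10000 shuffles (permutation p = 0.0015). Stretches of chromosome left from the embryonic stem cell strain in which Tal1 was targeted could give both, although the labels give 1 strain for both genotypes, and neighbours that share regulation stay open as a biological source. Of 1853 genes with several kept probes, 8 had 1 probe over 4-fold apart and another under 1.5-fold (Dapp1, Fgfr1op2, Hbb-bt, Inpp4b, Man2b1, Mcm6, Tm7sf3 and Vasp), and 6 of these probes were lower in SclRER/RER (one-sided exact binomial p = 0.145), too few to decide on sequence variants under probes. Of these 8 probes, the lower one of Man2b1 (limma adjusted p = 8.23e-06) and the higher ones of Dapp1 and Inpp4b passed. The other lower ones did not, with limma adjusted p between 0.069 and 0.25. On 18 probes SclRER/RER arrays lay over 8-fold apart while WT arrays stayed within 2-fold, against 0 the other way. These included probes of Hprt, Thumpd1, Fgfr1op2, Hbb-bt, Mcm6, Tm7sf3 and Vasp, so spread within SclRER/RER enters that count of lower probes.

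The Hbb-b2 probe rose by 5.19, while of 10 kept probes of Hbb-bs and Hbb-bt the 2 with at least 1 log2 unit of room under the highest value differed by 0.179 (SE 0.14, room 2.33) and -2.87 (SE 0.88, room 4.81). Both lay over 3 SE below what a rise of like size in those genes would give. For Hbb-bs this argues against such a rise read through shared signal. The Hbb-bt probe cannot decide for Hbb-bt. It read 10.05, 5.74 and 6.98 on the SclRER/RER arrays, while the other Hbb-bt probes, with little room, differed by -0.28 to 0.03. In WT the Hbb-b2 probe lay at 6.58, while the brightest probes of Hbb-bs and Hbb-bt lay at 14.88 and 14.97. These levels argue against the rise as signal shared with Hbb-bs or Hbb-bt RNA that stayed at its WT level. In the GRCm38.p6 table, built on C57BL/6J, Hbb-bs and Hbb-bt lie on the chromosome sequence and Hbb-b1 and Hbb-b2 do not, so a beta-globin haplotype of another strain is a candidate explanation. Of the 100 tested genes nearest to the cluster, 11 changed against 6.48% elsewhere (one-sided Fisher's exact p = 0.0613), which leaves this open. On chromosome 7 as a whole 10.5% of tested genes changed. The test therefore cannot tell a stretch at the cluster from the share of its chromosome. A first run anchored on Hbb-b1 and Hbb-b2, before the anchor was moved to Hbb-bs and Hbb-bt, did not pass either. A change in Hbb-b2 expression through SCL is untested here.

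Megakaryocyte genes were lower in SclRER/RER with camera at the preset correlation, but the list missed the threshold with an estimated correlation (adjusted p = 0.185). Under 5 other normalizations the list's median stayed at -0.707 or lower, which argues against the normalization as the source. The members chosen as markers of megakaryocytes and detected on all arrays (Alox12, Gp5, Pf4, Ppbp, Treml1 and Vwf) ranged from -0.87 for Gp5 to -1.88 for Ppbp. The next test takes them as made by those cells alone, which was not checked and need not hold for each. A test of 1 common fall, which a smaller share of megakaryocytic cells would give, had a p of 0.0162 over 100000 simulated draws that allow for the estimated errors, short of the 0.01 set for excluding it, after a chi-square approximation without that allowance had given 0.000512. A smaller share of such cells, which were not counted, and lower transcription in the mutant progenitors therefore cannot be told apart.

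The 6 arrays can be split into 3 and 3 in 10 ways, and 1 of the 10, the real one, gave as many as 762 changed probes, with 1 probe as the highest count of any other split. So few splits cannot give a share below 0.05.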
